A study of Rattus norvegicus with 8 samples.

How the data were processed

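Total RNA of extraocular muscles, the small muscles that move the eye, was measured on Affymetrix Rat Genome arrays, with 1 array per rat. The 8 adult Sprague-Dawley rats had an initial body weight of 200 ± 40 g, per the labels, and had been assigned at random to 2 groups of 4. The hyperthyroid group received 25 µg of triiodothyronine (T3, the active thyroid hormone) per 100 g of body weight by injection into the abdomen every other day for 6 weeks, and the muscles were taken 24 hours after the last injection. The control group was not given T3, and no sham injection is mentioned in the sources used here. The arrays are named here by group and by the number in their title: hyperthyroid 1, 2, 3 and 5, and control 7, 8, 9 and 11. The groups share no replicate number, so no pairing was tested.

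The deposited values are intensities on a linear scale, 1 per probe set and array, and the submitters' processing notes name GCOS, the scanner software of the array maker, with no version. Each deposited array had the same mean intensity after 2% of the values were trimmed at each end, 149.99 on each of the 8, so the values had already been scaled to each other. The medians differed between arrays, so the values were not quantile normalized. Whether detection calls or further filters were applied is not given in the sources used here. The table held 31099 probe sets, of which 57 were control probe sets of the manufacturer and were left out of the tests. Of the remaining 31042 probe sets, 20826 had 1 gene symbol in the platform annotation, 436 had several and 9780 had none. Probe sets with several symbols were not named. An identifier match was found for 20758 probe sets in a reference gene table of rat, used for names only, and 0 symbols needed an update.

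The values were set to at least 1 (1665 of 248792 values, or 0.669%, were lower) and taken to log2, with no further normalization. Probe sets in the upper 60% by mean log2 signal over the 8 arrays were kept, which left 18625 probe sets above a signal of about 28.2. A fold change of a dim probe set can be imprecise on this scale, and whether it is understated or overstated was not tested. The number of arrays also limits the precision. Hyperthyroid and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. A gene was represented by its probe set of highest mean signal, which gave 10446 genes. The 37 gene lists (pathways, fibre types and markers of other cell types) were tested with camera from limma, a test that compares a list with all other genes, at an inter-gene correlation of 0.01. Its p-values were adjusted over the 37 lists. Some lists share members, so their calls are not independent. Lum, for example, is in the extracellular matrix, hyaluronan and fibroblast lists, and Sdhb in the tricarboxylic acid cycle and respiratory chain lists. Member counts past the threshold are given over all probe sets and adjusted over the list alone. Array quality measures were compared by exact permutation tests of 4 against 4 arrays, two-sided, whose smallest possible p is 0.0286.

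The text names genes by a rule fixed, with the lists, tests and most alternatives, before the data were examined. The rule took the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold with no overlap between groups. It also took from each list up to 3 members with the smallest p past the threshold, or the 1 with the smallest p where none passed. Every measured sarcomeric myosin heavy chain gene of a fixed set, Thra, Thrb, Dio2, Atp2a1 and Atp2a2 completed it. Unnamed loci were left out of the first part. Dio2 did not pass the filter on dim probe sets and was not tested. The genes used to describe single arrays, and the 3 smallest p-values of each list that passed, were chosen after their values were seen.

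The alternatives fixed beforehand were quantile normalization, median centring, no filter, a filter at the upper 40%, 32 added before log2, eBayes without a trend or with a robust fit, array weights, the mean over a gene's probe sets, other thresholds, camera with an estimated correlation, fry, and leaving out each array in turn. After the arrays had been examined, a fit without the array labelled hyperthyroid 5 was carried through all settings as a second set of results, and the fits with a sex call or the Gapdh 3 prime to 5 prime ratio as a covariate, and without hyperthyroid arrays 1 and 2, were added. Of the 8 fits that leave out 1 array, the one without hyperthyroid 5 is the only one in which probe sets passed the threshold.

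The fits were tested on simulated data with the real means and spreads. With 200 changed probe sets among 18625, the fit on all 8 arrays recovered 22% of those changed 2-fold and 53% of those changed 4-fold at the threshold, with 4 false calls. Without hyperthyroid 5 the shares were 24% and 66%, with 7 false calls. In a simulation for camera on all 8 arrays, over 10446 genes, the 1 list of 25 genes shifted by 0.5 log2 was called, and 0 of 36 unshifted lists were. That simulation held no correlation between genes. No 2 arrays had identical values.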

Results

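Expression was measured in extraocular muscles of 8 adult rats, 4 made hyperthyroid with T3 for 6 weeks and 4 untreated, to learn how gene expression in these muscles differs in a chronic excess of thyroid hormone. Each array had a scaled mean signal of 149.99 after trimming, and median signals ran from 47.8 to 58.5.

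The array labelled hyperthyroid 5 lacked transcripts that were abundant on the other 7 arrays. Myh13, the extraocular myosin heavy chain, had a signal of 4.17 on it and between 5430 and 9340 elsewhere. The neonatal myosin Myh8 stood at 54.2 against 7599 to 12343, and the embryonic myosin Myh3 at 165 against 6412 to 15954. Myh4, the fast myosin of type IIB fibres, was at 24307, inside the range of the other arrays (16681 to 25104). The slow-fibre genes Myh7 and Myl3 stood at 13031 and 9380 on this array, above 4097 and 1421, the highest values elsewhere. Ankrd2 stood at 2059 against at most 155. The homeobox genes Hoxa10, Hoxa9 and Hoxd8 had signals of 399, 345 and 301 on it, against at most 27.8, 36.3 and 125 on the others. The oligodendrocyte gene Mobp and the glial gene Gfap were at 1.37 and 13.4 on it, and hyperthyroid 2 was also low in both (15.3 and 39.5), while the other 6 arrays had at least 1249 and 708. The first principal component held 22.9% of the variance, with hyperthyroid 5 at 98.04 and the other arrays between -35.6 and 8.80. The second held 20.9%, with hyperthyroid 2 at 86.1 and the other arrays between -39.9 and 21.6. The mean correlation with the other arrays was 0.848 for hyperthyroid 5 and 0.855 for hyperthyroid 2, against at least 0.877 for the rest. Hyperthyroid 2 thus also stood apart, and it was kept in both sets of results.

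**Figure D1:**
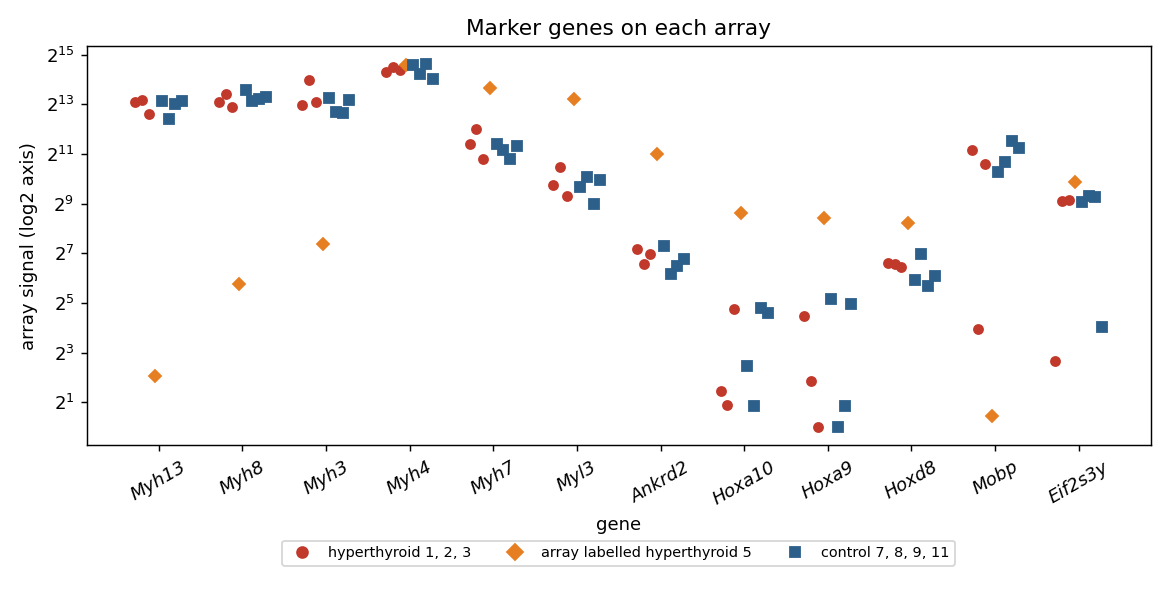
Signal of 12 marker genes on each of the 8 arrays, on a log2 axis, with 1 point per array (circles for hyperthyroid 1, 2 and 3, diamonds for the array labelled hyperthyroid 5, squares for control). Myh13, Myh8 and Myh3 lie at 4.17, 54.2 and 165 on hyperthyroid 5, while Myh4 at 24307 lies among the other arrays.

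RNA measures and sex-linked genes also varied. The ratio of the 3 prime to the 5 prime probe set of Gapdh, which is higher when RNA is shorter, was 3.91, 4.40, 2.18 and 1.44 on hyperthyroid 1, 2, 3 and 5, and 1.97, 1.68, 1.77 and 1.67 on control 7, 8, 9 and 11. The group means were 2.98 ± 1.40 (SD, n = 4) and 1.77 ± 0.136 (SD, n = 4), with an exact permutation p of 0.229. The corresponding Actb ratio had means of 4.92 ± 1.34 and 3.48 ± 0.344 (SD, n = 4 each; exact permutation p = 0.114). Eif2s3y, a gene of the Y chromosome, had signals of 6.32 on hyperthyroid 1 and 16.2 on control 11, and between 533 and 927 on the other 6 arrays. Xist, expressed from the inactive X chromosome, stood at 367 and 351 on the same 2 arrays and at no more than 44.5 elsewhere.

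No single gene passed the test between the 4 hyperthyroid and 4 control arrays. At an adjusted p under 0.05, limma called 0 of 18625 probe sets and 0 of 10446 genes, and the smallest adjusted p was 0.151. At an unadjusted p under 0.05 it counted 2151 probe sets, 1164 higher and 987 lower, where 931 would fall by chance. With median centring the split was 904 higher and 1245 lower. The genes closest to the threshold included Jund, a subunit of the AP-1 transcription factor, at a log2 difference of 0.82 ± 0.12 (SE), and Ctsd, which encodes the lysosomal protease cathepsin D, at -0.95 ± 0.15. With array weights in the fit, 6 probe sets passed.

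Without the array labelled hyperthyroid 5, a fit chosen after the arrays had been examined, limma called 29 probe sets, 10 higher and 19 lower, and 13 genes, 5 higher and 8 lower. With median centring the probe sets were 9 higher and 44 lower, and with quantile normalization 21 higher and 15 lower. Frat2, a regulator of Wnt signalling, rose by 1.505 ± 0.25 (log2 ± SE; adjusted p = 0.0440), Efr3a by 1.38 ± 0.16 (adjusted p = 0.0166) and Gpcpd1 by 1.24 ± 0.18 (adjusted p = 0.0252). Nrp1, a co-receptor for vascular endothelial growth factor, rose by 0.92 ± 0.15 (adjusted p = 0.0397), and Jund by 0.86 ± 0.11 (adjusted p = 0.0166), from a mean signal of 3656 ± 274 (SD, n = 4) in control to 6621 (n = 3). The genes that fell were Ciao2b (-1.25 ± 0.18), Laptm4a (-1.22 ± 0.16), Dnttip2 (-1.10 ± 0.16), Ctsd (-1.02 ± 0.15), Abra (-0.96 ± 0.15), Polr2k (-0.79 ± 0.13), Arl6ip5 (-0.73 ± 0.11) and Fxyd6 (-0.73 ± 0.12). Their adjusted p from limma ran from 0.0198 for Laptm4a to 0.0442 for Polr2k and Fxyd6. Laptm4a encodes a lysosomal membrane protein.

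Probe sets of one gene disagreed in several cases. Of the 29 called probe sets, 10 belonged to a gene with a brighter probe set, and the brighter one showed a median of 0.201 of the log2 difference. Glul, for glutamine synthetase, was at -1.14 on the called probe set and 0.01 on the brighter one. Pygm, the muscle glycogen phosphorylase, was at -1.30 and -0.43. Among the 13 genes, Efr3a was at 1.38 on its brightest probe set and at 0.10 and 0.16 on 2 others, Gpcpd1 at 1.24 and -0.25, and Dnttip2 at -1.10, 0.07 and 0.34. The calls also moved with single arrays. Leaving out a further array gave between 0 and 144 probe sets: 0 without hyperthyroid 1, control 8 or control 11, 2 without control 9, 9 without hyperthyroid 2, 11 without control 7 and 144 without hyperthyroid 3. With the Gapdh ratio as a covariate 1 probe set passed, which was none of the 29 (0 shared), and without a mean-variance trend 0 passed.

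**Figure D2:**
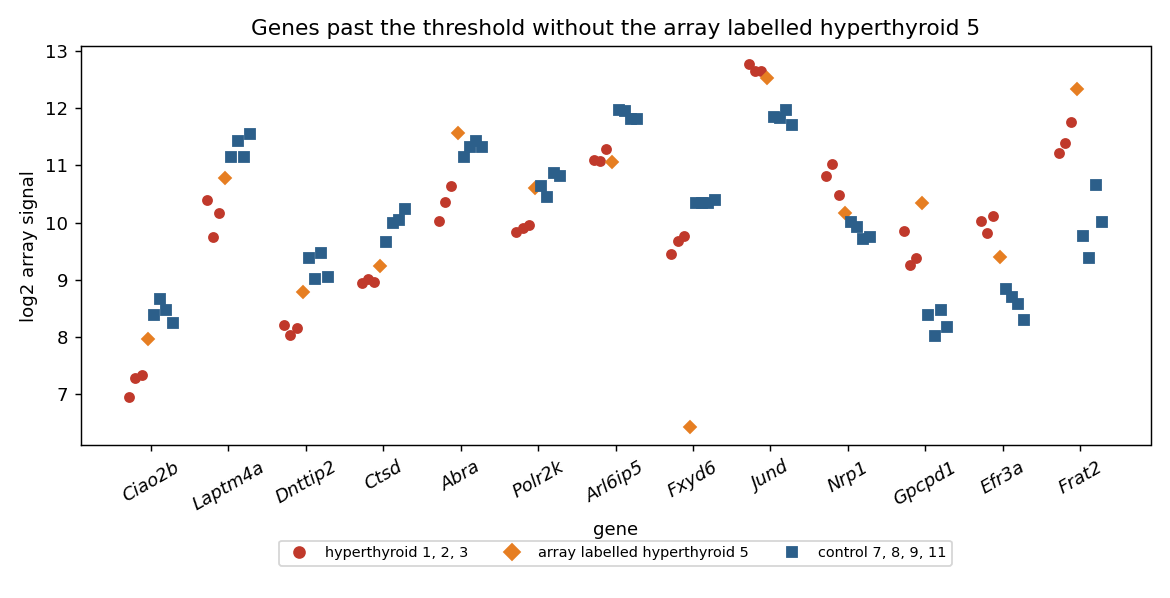
Log2 signal of the 13 genes past the threshold in the fit without the array labelled hyperthyroid 5, with 1 point per array (circles for hyperthyroid 1, 2 and 3, diamonds for hyperthyroid 5, squares for control), ordered by log2 difference from Ciao2b (-1.25) to Frat2 (1.505). Circles and squares do not overlap, and the left-out array lies among or above the control values for Polr2k and Abra.

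Among the 37 gene lists, camera called 7 on all 8 arrays, each lower in hyperthyroid arrays, and 5 of these concern energy metabolism, antioxidant defence or the proteasome. With quantile normalization 9 lists passed, 6 lower and 3 higher, the latter being slow fibre proteins (adjusted p = 0.0252), immediate early and heat shock genes (0.0370) and endothelial markers (0.0370). The tricarboxylic acid cycle list had 20 of 23 members lower, with a mean log2 difference of -0.25 (adjusted p = 3.1e-07). Its members with the smallest p were Sdhb, a succinate dehydrogenase subunit (-0.59 ± 0.12), Mdh2, mitochondrial malate dehydrogenase (-0.52 ± 0.12), and Got1 (-0.61 ± 0.14). The respiratory chain list had 56 of 71 members lower (mean -0.16, adjusted p = 3.6e-07), with Ndufb10 at -0.54 ± 0.11 and Ndufs8 at -0.45 ± 0.12. In the fatty acid oxidation list 20 of 29 members were lower (mean -0.19, adjusted p = 0.000376), with Decr1 at -0.56 ± 0.14, Ech1 at -0.73 ± 0.20 and Acadl at -0.41 ± 0.13. From the control mean this list lay at 0.07 on hyperthyroid 1, above all 4 controls (-0.05 to 0.04), and at -0.34, -0.25 and -0.23 on hyperthyroid 2, 3 and 5. The respiratory chain list lay at -0.09 on hyperthyroid 3 and at -0.14 on control 11. No member of these 3 lists passed the threshold over all probe sets. Adjusted over the list alone, 8 tricarboxylic acid cycle genes, 2 respiratory chain genes and 1 fatty acid oxidation gene passed, all lower. With an estimated correlation, the adjusted p was 0.381 for the tricarboxylic acid cycle, 0.622 for the respiratory chain and 0.381 for fatty acid oxidation, and no list of the 37 passed.

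The antioxidant list had 18 of 22 members lower (mean -0.21, adjusted p = 0.00208, and adjusted p = 0.381 with an estimated correlation). Gstm2, a glutathione transferase, stood at -1.04 ± 0.21 and the peroxidase Gpx4 at -0.47 ± 0.11, while Gpx3, the secreted peroxidase, stood at 0.67 ± 0.16. Adjusted over the list alone, 5 members were lower and 1 was higher. The proteasome list had 23 of 30 members lower (mean -0.13, adjusted p = 0.0138, and adjusted p = 0.912 with an estimated correlation), with Psmc6 at -0.38 ± 0.12, and 0 members passed adjusted over the list alone. Dimmer probe sets of Psmc6 stood at 0.57 (unadjusted p = 0.0189 in limma) and -0.12. The adjusted p of the proteasome list was 0.162 after quantile normalization and 0.155 without hyperthyroid 1. Its mean was -0.01 with the Gapdh ratio as a covariate (adjusted p = 0.903) and -0.02 without hyperthyroid 1 and 2 (adjusted p = 0.737), and on hyperthyroid 5 the list lay 0.11 above the control mean. Beside these 5 lists, the Gapdh ratio was above every control value on hyperthyroid 1, 2 and 3. The log2 difference also varied with signal, with a median of 0.15 in the dimmest of 5 equal bins of probe sets and -0.06 in the brightest (0.24 and -0.07 without hyperthyroid 5). Among 10000 lists matched on signal, the medians of the antioxidant and proteasome lists lay at percentiles 3.33 and 5.77 on all 8 arrays. Without hyperthyroid 5, the respiratory chain and antioxidant lists lay at 12.4 and 6.26.

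**Figure D3:**
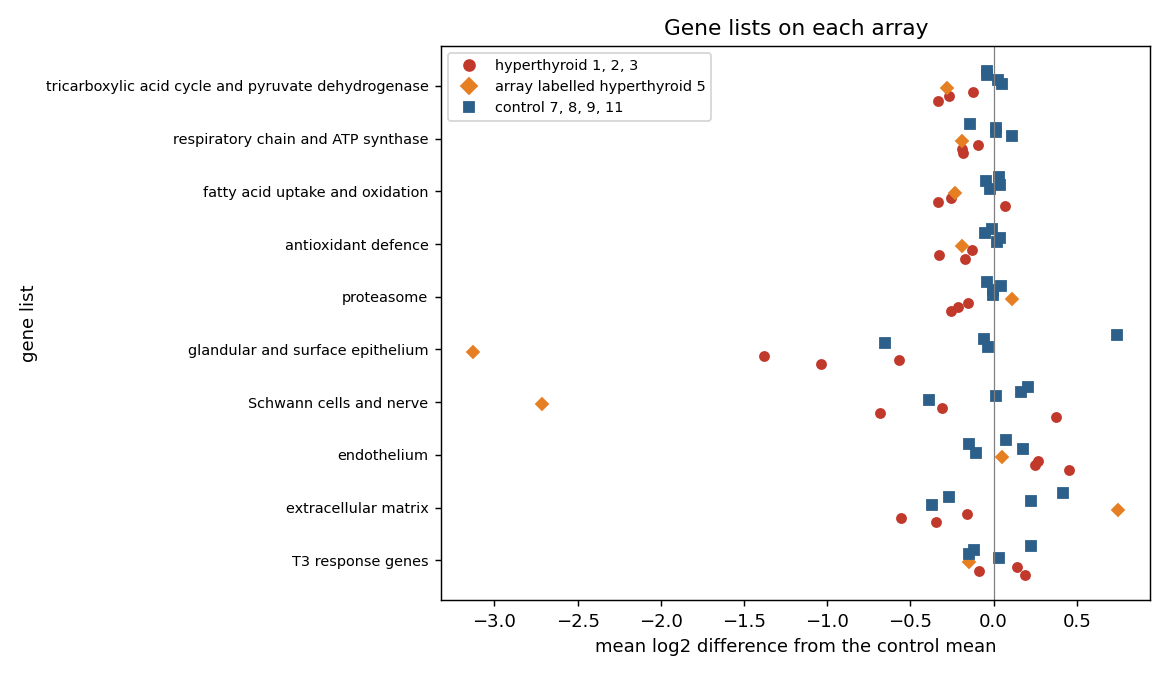
Mean log2 difference from the control mean over the members of 10 gene lists, with 1 point per array (circles for hyperthyroid 1, 2 and 3, diamonds for the array labelled hyperthyroid 5, squares for control). The tricarboxylic acid cycle list lies between -0.34 and -0.12 on the 4 hyperthyroid arrays, and the Schwann cell and nerve list lies at -2.71 on hyperthyroid 5.

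Markers of other cell types made up the other 2 lists. The glandular and surface epithelium list had 5 of 5 tested members lower (mean -1.53, adjusted p = 0.0237, and adjusted p = 0.381 with an estimated correlation), with Krt8 at -1.66 ± 0.60. Of the 18 genes fixed for this list, only 5 were tested. Krt8 signals were 9.24 to 70.5 on hyperthyroid arrays and 67.6 to 110 on controls. Epcam ran from 1.40 to 73.6 and from 8.84 to 410, and Spint1 from 6.275 to 57.5 and from 37.4 to 67.1. Some of these values lie below the filter level of 28.2, so the size of this mean is imprecise. On hyperthyroid 5 the list lay at -3.13. The Schwann cell and nerve list had 10 of 11 members lower (mean -0.83, adjusted p = 0.0264, and adjusted p = 0.912 with an estimated correlation), with S100b at -0.98 ± 0.46 and the myelin gene Mbp at -2.46 ± 1.22. Without hyperthyroid 5 the epithelium list had a mean of -0.99, with 5 of 5 members lower (adjusted p = 0.0934). In that fit it passed with no filter (0.0192), and when hyperthyroid 2 (0.0288) or control 8 (0.0363) was also left out. The Schwann cell and nerve list there had a mean of -0.21 (adjusted p = 0.634), with Mbp at -0.96 ± 0.58. The Mbp signal was 997 on hyperthyroid 2 and 61.4 on hyperthyroid 5, against 8526 and 7096 on hyperthyroid 1 and 3 and 4768 to 10668 on controls. The oligodendrocyte gene Mobp was low on the same arrays (15.3 and 1.37). The Mbp values therefore do not tell Schwann cells from oligodendrocytes. With hyperthyroid 5 kept, both lists also missed the threshold without control 11 (adjusted p = 0.0598 and 0.0624). For both lists, 0 members passed adjusted over the list alone.

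Without hyperthyroid 5, camera called 11 lists, 10 lower and 1 higher, and with an estimated correlation 0. Some other splits of these 7 arrays called as many or more, up to 15 for hyperthyroid 1, 3 and control 11 against the rest. Chance can therefore not be excluded for the number of lists in this fit. The 5 lists of metabolism, antioxidant defence and the proteasome were among the 11. The tricarboxylic acid cycle list had a mean of -0.24 (adjusted p = 3.1e-06, and adjusted p = 0.509 with an estimated correlation) and 22 of 23 members lower. With quantile normalization the mean of the respiratory chain list went from -0.15 to -0.05 (adjusted p = 0.310), and the antioxidant list missed the threshold (adjusted p = 0.0555). The antioxidant list also missed it with the Gapdh ratio as a covariate (mean -0.08, adjusted p = 0.358). The extracellular matrix list had 25 of 29 members lower (mean -0.35, adjusted p = 0.000293, and adjusted p = 0.684 with an estimated correlation), with Fn1, for fibronectin, at -0.87 ± 0.19, and its mean was 0.09 with the Gapdh ratio as a covariate. The hyaluronan and proteoglycan list stood at a mean of -0.33, leukocyte markers at -0.42, fibroblast markers at -0.25, and the creatine and adenine nucleotide list at -0.25 (adjusted p = 0.0160, 0.0207, 0.0402 and 0.0155). With an estimated correlation the adjusted p was 0.684 for the first 3 and 0.509 for the creatine list. With the Gapdh ratio as a covariate the means of the first 3 were 0.07, 0.10 and 0.42, and on all 8 arrays leukocyte markers were at -0.05. Quantile normalization ended the call of the fibroblast and creatine lists (adjusted p = 0.179 and 0.156). Endothelial markers were higher in 9 of 10 members (mean 0.32, adjusted p = 0.0155, and adjusted p = 0.383 with an estimated correlation). Kdr, the main receptor for vascular endothelial growth factor, stood at 0.73 ± 0.14, and 2 endothelial members passed adjusted over the list alone. On all 8 arrays the endothelial list had an adjusted p of 0.0503.

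Some of these calls without hyperthyroid 5 were lost when a further array was left out. Leaving out hyperthyroid 2 gave means of -0.17 for hyaluronan and proteoglycans, -0.23 for leukocytes and -0.13 for fibroblasts (adjusted p = 0.114, 0.212 and 0.175). Without control 11 the hyaluronan list was at -0.20 and fibroblasts at -0.11 (adjusted p = 0.0918 and 0.122), and without control 8 leukocytes were at -0.33 and fibroblasts at -0.15 (adjusted p = 0.0978 and 0.166). Without hyperthyroid 1 the fibroblast and creatine lists missed the threshold (adjusted p = 0.158 and 0.0529). Adipocyte markers had a mean of -0.595 without hyperthyroid 5 and did not pass (adjusted p = 0.0934). They stood at -0.86 on hyperthyroid 1, -1.30 on hyperthyroid 2, 0.37 on hyperthyroid 3 and 0.99 on hyperthyroid 5. They passed without hyperthyroid 3 (mean -1.08, adjusted p = 0.000999) and without control 11 (mean -0.70, adjusted p = 0.0303).

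The list of genes known to respond to T3 did not pass the test on all 8 arrays, with 8 of 17 members higher and 9 lower (mean 0.02, median -0.07, adjusted p = 0.735). Its member with the smallest p was Hr, a corepressor induced by thyroid hormone in other tissues, at 1.08 ± 0.30, with signals of 143 ± 59.3 in hyperthyroid and 64.3 ± 9.64 in control arrays (SD, n = 4 each; adjusted p = 0.275 in limma). Adjusted over the list alone, 0 members passed. At an unadjusted p under 0.05 in limma, 4 members were higher and 0 lower. The receptor genes Thra and Thrb stood at 0.10 ± 0.23 and 0.49 ± 0.19. The list of thyroid hormone transport, deiodination and receptor genes had a mean of 0.07 (adjusted p = 0.826), and the transporter Slc7a8 stood at 0.92 ± 0.35.

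Contractile protein lists did not pass on all 8 arrays with the values as deposited and no covariate. The fast fibre list had a mean of -0.07 (adjusted p = 0.381) and the developmental, cardiac and extraocular list one of -0.61 (adjusted p = 0.381). The slow fibre list had a mean of 0.36 (adjusted p = 0.0891, and adjusted p = 0.912 with an estimated correlation). The slow fibre list passed without hyperthyroid 1 (mean 0.49, adjusted p = 0.0172) and without hyperthyroid 3 (mean 0.58, adjusted p = 0.00122), and with the Gapdh ratio as a covariate (mean 0.65, adjusted p = 0.00704). With that covariate the developmental list also passed (mean -1.84, adjusted p = 1.9e-05). The covariate fit leans on hyperthyroid 5, the only hyperthyroid array whose ratio was not above every control. The slow fibre list lay at 1.34 on it and the developmental list at -3.27. Myh4 stood at 0.08 ± 0.16, Myh1 at -0.07 ± 0.23 and Myh2 at 0.31 ± 0.23, and the calcium pumps Atp2a1 and Atp2a2 at -0.26 ± 0.13 and 0.42 ± 0.21. Array hyperthyroid 5 set the values of the other myosins. Myh13 was at -2.68 ± 1.99 with it and 0.04 ± 0.19 without it, Myh8 at -2.02 ± 1.35 and -0.18 ± 0.15, Myh3 at -1.09 ± 1.11 and 0.41 ± 0.23, Myh7 at 0.79 ± 0.47 and 0.23 ± 0.23, and Myh6 at -0.14 ± 0.65 and 0.67 ± 0.28. A dimmer probe set of Myh7 stood at 0.004 with that array and at -0.73 without it (unadjusted p = 0.0864 in limma). Without hyperthyroid 5, the slow fibre list had a mean of 0.03 and the developmental list one of 0.28. The fast fibre list there had a mean of -0.15 (adjusted p = 0.0934), and it passed with the Gapdh ratio as a covariate (adjusted p = 0.000440), with array weights (0.0171), and when hyperthyroid 2 (0.000436) or control 11 (0.00506) was also left out. The adjusted p in limma of each of these myosins was above the threshold in both fits.

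The remaining lists did not pass on all 8 arrays with the values as deposited, no covariate and no array weights. Their adjusted p ran from 0.0529 for immediate early and heat shock genes (mean 0.32) to 0.979 for myogenic regulation (mean -0.12, median 0.07). The immediate early and heat shock list passed without hyperthyroid 2, hyperthyroid 3 or control 9 (adjusted p = 0.0465, 0.0205 and 0.0203) and with the sex call as a covariate (0.0455). The endothelial list passed without control 8 or control 11 (0.0138 and 0.0442), the creatine list without control 11 (0.0304) and the hyaluronan list without control 7 (0.0393). With array weights the endothelial and creatine lists passed (adjusted p = 0.0252 for each), and the endothelial list also passed with the sex call (0.0455). The member of smallest p in the myogenic list was Mstn, for the growth inhibitor myostatin, at -1.66 ± 0.43, and it passed adjusted over the list alone. Eno1 of the glycolysis list stood at -0.78 ± 0.16, and Dgat2, a triglyceride synthesis enzyme of the lipogenesis list, at 1.23 ± 0.29. A dimmer probe set of Dgat2 stood at 0.38, and at 0.15 without hyperthyroid 5. Pln, for phospholamban, stood at -1.33 ± 0.45, and at -0.76 ± 0.17 without hyperthyroid 5, whose signal was 161. A dimmer probe set of Pln stood at -0.25, and at 0.08 without that array. Dok7 of the neuromuscular junction list stood at 0.98 ± 0.24 and Lum, for lumican, at -0.92 ± 0.29. The mean and the direction of the test differed in sign for the atrophy and autophagy list (mean 0.05, lower in camera; adjusted p = 0.855).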

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

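The test of Hox genes, the tests on T3 treatment and on a failed array, the test of hyperthyroid 5 alone, the test of RNA integrity on single probe sets, and the splits for the adjusted count on all 8 arrays were chosen after the results were seen. In 22 of 198 groups of 4 arrays, 1 array lay farther from the other 3 than the 95% limit of a Dixon test allows, where chance gives about 1 in 20, and 8 of the 22 were on hyperthyroid 5.

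On the array labelled hyperthyroid 5, the log2 signals of Myh13, Myh8 and Myh3 were 2.06, 5.76 and 7.37, and the developmental, cardiac and extraocular list lay at -3.27 and the neuromuscular junction list at -1.74 from the control mean. The treatment as the reason is argued against by the other 3 hyperthyroid arrays, whose mean for these 3 myosins was 0.0911 log2 above control. Degraded RNA or a failed array is argued against by its Gapdh ratio of 1.44, the lowest of the 8, and by Myh4, 0.21 log2 from the control mean. A candidate explanation is that this RNA came from a limb or trunk muscle: of the 22 Hox genes measured, with no filter, 13 were highest on this array and at most 3 on any other. Of the same 22, 15 were above the filter level of 28.2 there and between 1 and 9 elsewhere. The test was chosen after these genes had been seen, so the source of this RNA stays a hypothesis.

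The tricarboxylic acid cycle list was lower on all 4 hyperthyroid arrays, and it kept 0.964 of its mean difference without hyperthyroid 5, which argues against that array alone. With the Gapdh ratio as a covariate the list kept 0.914 on all 8 arrays but 0.423 without hyperthyroid 5 (mean -0.10), with a camera p of 3.7e-06 and 0.0115. The share of 0.914 rests largely on hyperthyroid 5, where the list lay at -0.28 and the ratio was not above the controls. As the source of that RNA is in doubt, this share says little about RNA integrity in extraocular muscle. Less than 0.5 was kept in 1 of the 2 fits and p stayed under 0.05 in both, so lower RNA integrity and the T3 treatment cannot be told apart for it: the 3 other hyperthyroid arrays all had higher ratios than any control. Among 10000 lists matched on signal, its median lay at percentile 0.80 on all 8 arrays and 2.52 without hyperthyroid 5, and matched lists lack the correlation between its genes (0.194), and the requirement that both fits give the same reading was set afterwards, so an offset that depends on signal stays open too. The percentiles were 1.38 and 12.4 for the respiratory chain, 3.33 and 6.26 for the antioxidant list, and 5.77 and 1.45 for the proteasome, so the offset stays open for these 3. Fatty acid oxidation lay below the central 95% of its matched lists in both fits (percentiles 0.110 and 1.16). Its matched lists also lack the correlation between its genes (0.109 on all 8 arrays), so the offset is not excluded for it either. Of the 35 splits of the 8 arrays, 23 called at least 7 lists and the highest other split called 13, so chance cannot be excluded for the number of lists.

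Without hyperthyroid 5, 29 probe sets were called and no other of the 35 splits of 7 arrays called any (1 of 35 gave as many, highest other 0). The array left out was picked after the arrays had been seen, and no other fit that leaves out 1 of the 8 arrays called any. The splits do not account for that choice, so chance is not excluded for that count. At an unadjusted p under 0.05 the count was 2840, against 2064 in the highest other split (1 of 35). Lower RNA integrity may account for part: with the Gapdh ratio as a covariate the called probe sets kept a median of 0.803 of their log2 difference, while the median SE went from 0.158 to 0.273. Of the 29, 24 had an unadjusted p under 0.05 with the covariate and 0 passed after adjustment, and brighter probe sets of 10 of the genes showed 0.201. The 29 were selected for their difference on these same arrays. That choice alone favours a low p with the covariate and a smaller difference on other probe sets. The position of the probe sets in the transcript was not examined. These tests therefore cannot decide, and RNA integrity and T3 cannot be told apart for these probe sets. On all 8 arrays 2151 probe sets had an unadjusted p under 0.05, against 1772 in the highest other split (1 of 35), and 0 passed after adjustment, as in all 35 splits (highest other 0).

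Other single arrays stood apart as follows, in log2 signal. Decr1 was 9.47 on hyperthyroid 5, and on hyperthyroid 2 Klf15 was 9.07, Slc4a1 6.14, Tef 8.62 and Uty 5.61. Among controls, Dok7 was 8.22 and Tpm3 11.05 on control 7, and Gpx3 was 9.52, Myh2 14.08 and Thra 6.75 on control 8. Hr was 6.30 and Psmc2 11.82 on control 9. As mean differences from control, the glycogen list was -0.26 on hyperthyroid 1, the respiratory chain list -0.0921 on hyperthyroid 3, and the cartilage, bone and tendon list 1.79 on hyperthyroid 5. The Actb ratio was 2.97 on control 11, and the median signal 49.2 on hyperthyroid 5.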

How the results depend on the processing

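The fits without hyperthyroid 5, without hyperthyroid 1 and 2, and with covariates were chosen after seeing the data. The cause of a changed call was not tested unless fewer arrays or genes show it, and probe sets near background are limited by their signal.

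On all 8 arrays the count of probe sets past the threshold stayed at 0 under quantile normalization, median centring, both filters, 32 added, no trend, a robust fit, the sex call and the other thresholds. Array weights gave 6 probe sets and 4 genes, the Gapdh ratio 8 and 6, and leaving out hyperthyroid 1 and 2 gave 3 and 2. Leaving out each array gave 0 to 29 probe sets and 0 to 13 genes, and 7 to 11 lists. The 7 lists, all lower, became 9 (6 lower, 3 higher) with quantile normalization, 0 with an estimated correlation, 2 with fry, 17 with the Gapdh ratio and 13 without hyperthyroid 1 and 2.

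With an estimated correlation the adjusted p was 0.381 for the tricarboxylic acid cycle, fatty acid oxidation, antioxidant and epithelium lists, 0.622 for the respiratory chain, and 0.912 for the proteasome and Schwann cell lists. With fry it was 0.176 for fatty acid oxidation, respiratory chain and epithelium, 0.602 for the proteasome and 0.869 for Schwann cells. The proteasome list had 0.162 with quantile normalization, 0.903 with the Gapdh ratio and 0.737 without hyperthyroid 1 and 2. The Schwann cell list had 0.0535 with the 40% filter, 0.0517 without a trend, 0.0536 with a robust fit and 0.110 with array weights. Over left-out arrays the adjusted p ran from 7.5e-06 to 0.155 for the proteasome, 0.000163 to 0.634 for Schwann cells and 0.00566 to 0.0934 for epithelium. The tricarboxylic acid cycle, respiratory chain, fatty acid oxidation and antioxidant lists stayed past the threshold whichever array was left out.

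With the Gapdh ratio on all 8 arrays, 3 lists turned to higher: extracellular matrix (adjusted p = 0.000636), leukocytes (0.00533) and adipocytes (0.00704). Without hyperthyroid 1 and 2, leukocytes (0.0315) and adipocytes (0.00166) did too. With the ratio, 8 further lists passed: developmental (1.9e-05), neuromuscular junction (2.4e-05) and mitochondrial biogenesis (0.0180) lower, and slow fibre (0.00704), lipogenesis (0.00749), interferon (0.00749), cartilage (0.0285) and immediate early genes (0.0349) higher. Of these, 5 also passed without hyperthyroid 1 and 2, from 0.00263 for neuromuscular junction to 0.0362 for mitochondrial biogenesis. Both fits lean on hyperthyroid 5, the only hyperthyroid array whose Gapdh ratio (1.44) was not above every control. On that array the developmental list lay at -3.27, neuromuscular junction at -1.74, slow fibre at 1.34 and leukocytes at 1.08 from the control mean. The calls in these fits are therefore no evidence of a T3 effect apart from that array.

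Without hyperthyroid 5, the 29 probe sets and 13 genes became 53 (9 higher, 44 lower) and 21 (5 higher, 16 lower) with median centring, 71 and 29 without a filter, 85 and 40 with the 40% filter, 79 and 37 with 32 added, 0 and 0 without a trend, 1 and 0 with the Gapdh ratio, 204 and 107 at an adjusted p under 0.1, and 0 and 0 at 0.01. The mean over probe sets gave 6 genes. Leaving out a further array gave 0 to 144 probe sets and 0 to 64 genes. The 11 lists became 7 with quantile normalization, 0 with an estimated correlation and 1 with fry. With the Gapdh ratio there, the slow fibre (adjusted p = 5.6e-06), developmental (0.0243), lipogenesis (0.00112), extracellular matrix (0.672), hyaluronan (0.981), leukocyte (0.968) and fibroblast (0.146) lists changed direction, and fast fibre (0.000440), excitation-contraction coupling (0.00147) and epithelium (0.0395) passed as lower. The slow fibre list also did without hyperthyroid 2 (0.0225), and over left-out arrays its adjusted p ran from 0.0225 to 0.772.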

Other observations

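The list of myelin and glial genes and the list of lysosomal genes were written after the data had been seen. Myelin and glial genes (13 measured, among them Mobp, Mog, Cldn11 and Gfap) had all 13 members lower, with a mean log2 difference of -2.18 on all 8 arrays and -1.18 without hyperthyroid 5. The list holds the genes whose low values prompted it, so its camera p of 4.7e-07 on all 8 arrays and 0.000463 without hyperthyroid 5 (0.171 and 0.334 with an estimated correlation) was set aside. The difference came from 2 arrays: the list stood at -5.18 on hyperthyroid 5 and -3.55 on hyperthyroid 2, against 0.08 on hyperthyroid 1, -0.07 on hyperthyroid 3 and between -0.67 and 0.42 on the controls. Ptgds, a prostaglandin D synthase abundant in the meninges, had signals of 41.4 on hyperthyroid 2 and 13.9 on hyperthyroid 5, against at least 2877 elsewhere.

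Ctsd, Laptm4a and Npc2, which act in lysosomes, had been seen among the smaller p-values, and a hypothesis was that lysosomal genes as a group may be lower in hyperthyroid arrays. The 30 other lysosomal genes measured had a mean of -0.08, with 17 lower and 13 higher, and a camera p of 0.256 on all 8 arrays. Without hyperthyroid 5 the mean was -0.14 and p = 0.0471, or p = 0.467 with an estimated correlation. The 2 fits fall on different sides of 0.05, so the hypothesis stays undecided.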
